A study of Mus musculus with 12 samples.

How the data were processed

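The samples are 4 transcriptome libraries and 4 B cell receptor libraries of primary mammary tumours of MMTV-PyMT mice, 2 of each kind from untreated and 2 from entinostat-treated samples, per the labels. Tumours were dissociated with collagenase at 37 °C and run on the 5′ version 2 droplet chemistry of 10x Genomics, per the labels' protocols. T cell receptor samples are not analysed here. The labels number the samples of each treatment but nothing in them says that the replicates come from separate animals, so p-values measure only the spread between these samples, which may be technical.

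The deposited transcriptome matrices hold raw UMI counts per gene and cell barcode (integer matrices per the file headers), filtered to barcodes with at least 500 UMIs as the values show, for 32285 genes. The deposited receptor tables hold UMI and read counts per assembled contig, productive contigs only. Reads were processed with Cell Ranger 7.1.0 on build mm10, per the submitters' processing notes. Groups were taken from the labels and each file from the sample it was deposited under. Total UMI counts per transcriptome library lay between 68922191 and 95124658.

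The cell filter, cluster settings, marker genes of 16 cell classes, 46 gene lists, 174 ligand-receptor pairs, the rule for named genes, the tests and most alternatives were fixed before the data were examined. Cells were kept with at least 500 UMIs, at least 200 detected genes and at most 15% mitochondrial UMIs. Doublets were marked per library with Scrublet (through Scanpy 1.11.5) and removed, 512 cells in all and 1.84% to 2.06% of each library. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with the library as batch key, and 30 principal components and a graph of neighbours shared among the 15 nearest were clustered with the Leiden algorithm at resolution 1 (leidenalg). No batch integration was applied.

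The 33 clusters were named from the fixed markers, a marker counting as detected in a cluster when at least 25% of its cells had a UMI of it. A cluster was left unnamed with under 3 detected markers, with more markers of another class among its 10 leading genes, with a second class scoring above 70% of the first, or with a median UMI count under 33.3% of its library's without any marker among those genes. The score that ranks classes was changed once after the clusters had been seen, and the cell class names are rebuilt from these markers, not taken from the authors. In all 27 clusters were named and 6 were left unnamed, holding 9.31% of untreated and 8.13% of entinostat cells. Ambient RNA was not removed, since that needs barcodes outside the cells, which were not used here.

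Shares of each class per library were given 95% Wilson intervals, which cover counting error only, and compared by exact two-sided permutation tests. UMI counts were summed per library and class for the 7 classes with at least 50 cells in each library, the cells themselves not being replicates. Sums were tested per class with edgeR 4.0.16 (filterByExpr, TMM normalization, quasi-likelihood F-test) under R 4.3.3, with Benjamini-Hochberg adjustment within the class and a threshold of 0.05. Depths of these sums ran from 473612 to 59501028 UMIs. Levels are CPM on TMM-scaled library sizes, and changes are log2 ratios of entinostat over untreated with their standard errors.

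Gene lists with at least 4 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2, and adjusted over all 177 tests of a list in a class. Counts adjusted over the list alone use the members' own p-values. Ligand-receptor combinations were kept where both genes reached 20 CPM in at least 2 libraries, with CPM scaled over all genes without the filter on low counts, and the sum of log2(CPM + 1) was tested with limma (moderated test with trend). Receptor libraries were summarised as cells with a productive heavy chain, their isotypes and the share of cells in clonotypes of at least 2 cells, with the count of 0 read as allowing 3 counts.

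The genes named per class are the 5 with the largest change in each direction (3 outside the 3 largest classes) that passed the threshold, had both entinostat libraries on the same side of both untreated libraries, a mean of at least 50 CPM and at least 20% of the level of the class where the gene is highest; predicted genes, receptor segments, mitochondrial, ribosomal and haemoglobin genes were passed over. To these come the 4 members with the smallest adjusted p of each list that passed, of which a selection is printed, 9 genes fixed in every class, and the 5 ligand-receptor combinations of smallest p in each direction.

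The tests were tried on simulated counts for the real genes with 200 changed genes. With the fitted dispersions, 2-fold changes were recovered in 23.0% (neutrophil-like, 5429 genes) to 74.0% (macrophage-like, 12301 genes) of cases, and genes without a change made up 0.893% (neutrophil-like) to 15.3% (macrophage-like) of the calls, the latter above the nominal rate. A second simulation with dispersions redrawn around the trend, added after that result, gave 0% (epithelial-like, 16147 genes) to 69.0% (endothelial-like, 11144 genes) recovery of 2-fold changes and at most 7.82% false calls (endothelial-like); 4-fold changes in epithelial-like cells were recovered in 83.0% and 0% of cases under the 2 schemes. Among the 1534 ligand-receptor combinations, 26.0% of log2 changes of 1 and 86.0% of those of 2 were recovered, with 7 unchanged combinations called. Lists shifted 1.5-fold were recovered in all classes except for 1 of 5 in neutrophil-like cells, and 0 lists without a shifted gene were called. These simulations drew genes and combinations independently of one another. They therefore say nothing about false calls where members of a list vary together, as with G2/M genes in mural-like cells (estimated correlation 0.885).

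Alternatives were DESeq2 1.42.0, no filter on low counts, the replicate number as a block, leaving out each library, doublets kept, stricter cell filters (1000 UMIs, 500 genes, 10% mitochondrial UMIs), clustering per library, Leiden resolution 0.5, leaving out genes under 10% of their highest class, thinning to the lowest library total of each class, other denominators, estimated correlations, fry, pseudocounts and expression minima. Added after the data were seen were a robust quasi-likelihood fit, DESeq2's size factors within edgeR, and ligand-receptor combinations at 20% of the highest class. No annotation of coordinates was used.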

Results

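Primary mammary tumours of MMTV-PyMT mice, in which the polyoma virus middle T antigen drives carcinoma of the mammary epithelium, were profiled by droplet single-cell RNA sequencing from the 5′ end of transcripts. Samples came from untreated mice or from mice given entinostat, an inhibitor of class I histone deacetylases, with 2 transcriptome libraries and 2 B cell receptor libraries per treatment. The series concerns the inference of communication between cell types from such data. The transcriptome libraries held 10422, 9910, 16780 and 11214 barcodes (untreated 1, untreated 2, entinostat 1 and entinostat 2) and 68922191, 70539489, 95124658 and 76335756 unique molecular identifiers (UMIs). Barcodes above 15% mitochondrial UMIs made up 41.4%, 28.9%, 57.9% and 49.5% of these libraries, so that more barcodes were left out of the entinostat libraries. The 25377 cells kept (5992, 6898, 6926 and 5561) had median depths of 8351, 7783, 10178 and 9621 UMIs. The 4 libraries differed from one another beyond sampling noise, with a chi-square per degree of freedom of 29.5 between the untreated libraries, 86.9 between the entinostat libraries and 89.6 to 109 between treatments.

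Which cell types changed in abundance was asked first. Fibroblast-like cells, the collagen-producing cells of the tumour stroma, made up 2.53% ± 0.0663 of untreated cells and 6.24% ± 1.88 of entinostat cells (mean ± SD, n = 2 libraries each). Their shares were 2.49% (95% Wilson interval 2.12 to 2.91) and 2.58% (2.23 to 2.98) in the untreated libraries, and 4.91% (4.42 to 5.44) and 7.57% (6.90 to 8.30) in the entinostat libraries. Endothelial-like cells, which line vessels, stood at 5.41% ± 1.02 in untreated and 7.85% ± 1.18 in entinostat libraries. Macrophage-like cells stood at 15.6% ± 0.224 and 12.5% ± 0.00410. Mural-like cells, the pericytes and smooth muscle of vessel walls, made up 3.14% ± 0.994 and 4.2% ± 0.106, and neutrophil-like cells 5.43% ± 0.0455 and 5.10% ± 0.0862. The treatments did not overlap in these 5 classes, and each exact two-sided permutation test gave p = 0.333, the smallest that 2 libraries against 2 can give. Epithelial-like tumour cells (52.9% ± 1.02 and 49.0% ± 9.69) and T/NK-like lymphocytes (4.35% ± 0.356 and 4.71% ± 2.45) overlapped between treatments (exact permutation p = 1.0). As shares of the cells other than epithelial, fibroblast-like cells made up 5.39% ± 0.258 and 12.1% ± 1.39, and macrophage-like cells 33.2% ± 0.245 and 24.9% ± 4.74. Mural-like shares of these cells overlapped between treatments (6.70% ± 2.26 and 8.37% ± 1.38, exact permutation p = 0.667). Neutrophil-like shares of them (11.5% ± 0.154 and 10.2% ± 1.76) did not overlap, but did with doublets kept, at Leiden resolution 0.5 and with each library clustered on its own (exact permutation p = 0.667 each). The removal of barcodes rich in mitochondrial RNA, which was heavier in the entinostat libraries, can set such shares.

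**Figure D1:**
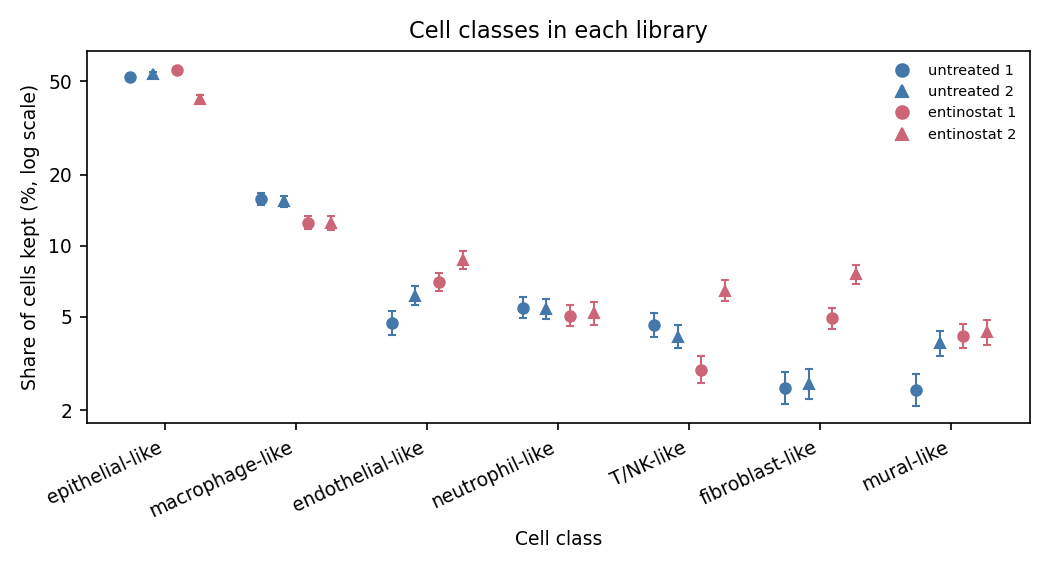
Share of the cells kept (percent, log scale) in each of 7 cell classes, with 1 point per library and bars for the 95% Wilson interval, which covers counting error only. The fibroblast-like shares were 2.49% and 2.58% in the untreated libraries and 4.91% and 7.57% in the entinostat libraries.

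The next question was how expression inside each class differed between treatments, here first for fibroblast-like cells. Crabp1, which encodes a cytosolic binding protein for retinoic acid, rose from 244 ± 7.11 to 1296 ± 71.3 counts scaled to a common library total (CPM; mean ± SD, n = 2 libraries each), a log2 change of 2.41 ± 0.11 (SE). Moxd1 (23.8 ± 7.47 to 89.2 ± 19.9 CPM) and Uck2, a uridine-cytidine kinase (83.2 ± 2.67 to 174 ± 3.49 CPM), rose by log2 changes of 1.90 ± 0.24 and 1.06 ± 0.11. Dmkn and Sbsn, which encode secreted proteins best known from the epidermis, fell from 133 ± 6.60 to 4.59 ± 2.07 CPM and from 169 ± 18.3 to 38.2 ± 14.5 CPM (log2 changes of -4.92 ± 0.23 and -2.16 ± 0.24). Car3, a carbonic anhydrase abundant in fat cells, fell from 82.2 and 395 CPM in the untreated libraries to 1.21 and 0.329 CPM. No cluster was named as fat cells, so the naming rule could not screen Car3 against such cells. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.000304 for Crabp1 and Dmkn, 0.0359 for Moxd1, 0.0336 for Car3 and 0.0332 for Uck2 and Sbsn. In all, 8 genes rose and 20 fell of 11467 tested (DESeq2 called 129), and the treatments were apart in 44.2% of genes against 33.3% by chance. Genes share differences between libraries and other splits of the libraries were not counted, so in every class such a share is descriptive only. Without entinostat 1 the count was 661 and without entinostat 2 it was 473; 10 of the 28 calls were kept without untreated 1 and 15 without untreated 2. Without untreated 1 the calls of Moxd1 (log2 change 1.61) and Uck2 (1.10) ended, and so did that of Uck2 without untreated 2 (1.03). A robust fit ended the calls of Car3 (adjusted p = 0.379) and Sbsn (adjusted p = 0.0598, 0.0332 in the standard fit).

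Other called genes of the fibroblast-like class, picked here after their values were seen, included further fat cell genes. Adipoq, the gene of the hormone adiponectin, stood at 21.4 and 72.6 CPM in the untreated and 0.485 and 0.165 CPM in the entinostat libraries. Pck1, an enzyme of gluconeogenesis and glycerol synthesis, stood at 7.30 and 12.6 CPM in the untreated libraries and at 0 in both entinostat libraries. Il1rl1, the receptor for interleukin 33, stood at 30.2 and 29.0 CPM against 1.70 and 2.31 CPM. Tnfaip6, a hyaluronan-binding protein induced by inflammation, fell from 917 ± 47.2 to 389 ± 65.7 CPM (log2 change -1.24 ± 0.14, n = 2 libraries each, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0332). Without untreated 1 the calls of Pck1 (adjusted p = 0.0642) and Tnfaip6 (log2 change -1.18) ended, and so did that of Pck1 without untreated 2 (adjusted p = 0.146). The call of Adipoq ended with a robust fit (adjusted p = 0.244), and those of Adipoq and Pck1 with libraries thinned to the lowest total (adjusted p = 0.0607 and 0.0520). With each library clustered on its own, neither Adipoq nor Pck1 was among the genes tested in this class. Among markers of other cell types in this class, 10 of 10 epithelial markers were higher (median log2 change 0.38). Lower were 4 of 4 fat cell (-7.76), 4 of 5 neutrophil (-1.10), 6 of 8 macrophage (-0.32) and 5 of 8 mural markers (-0.55). Fat cells or their RNA among the untreated fibroblast-like cells thus stay open as the source of Car3, Adipoq and Pck1. This was not tested, since no cluster was named as fat cells. Crabp1 is among the 10 genes that lead the larger fibroblast-like cluster.

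Gene groups of cancer-associated fibroblasts moved in opposite directions. All 10 measured genes of the contractile, matrix-producing (myofibroblastic) group were higher with entinostat, with a median log2 change of 0.51. Of these, 8 passed when adjusted over the list alone and 0 when adjusted over all genes. They included the collagen gene Col12a1 (1439 to 2234 CPM, log2 change 0.63 ± 0.09), the matrix protein gene Postn (4490 to 6331 CPM, 0.50 ± 0.09) and Thbs2, a thrombospondin (613 to 910 CPM, 0.57 ± 0.12). Of 12 genes of the inflammatory fibroblast group, 10 were lower (median log2 change -0.68); 5 lower and 1 higher passed when adjusted over the list alone and 0 over all genes. Has1, a hyaluronan synthase, went from 159 to 53.8 CPM (log2 change -1.57 ± 0.26), Ly6c1 from 366 to 139 CPM (-1.40 ± 0.23) and the neutrophil chemokine gene Cxcl1 from 524 to 345 CPM (-0.60 ± 0.10), whereas Pi16, a marker of resting fibroblasts, went from 591 to 880 CPM (0.57 ± 0.13). By limma's camera test with a preset correlation of 0.01, the myofibroblastic group rose (Benjamini-Hochberg adjusted p = 4.62e-06) and the inflammatory group fell (adjusted p = 0.00526), and for each adjusted p = 0.953 with an estimated correlation. Without untreated 1 the call of the inflammatory group ended (median log2 change -0.59).

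In the macrophage-like class, Gpnmb, which encodes a transmembrane glycoprotein of lipid-laden macrophages, fell from 671 ± 46.4 to 192 ± 35.7 CPM (mean ± SD, n = 2 libraries each; log2 change -1.80 ± 0.14, SE). Hspa1b, an inducible 70-kDa heat shock protein, rose from 44.5 ± 2.68 to 132 ± 15 CPM (1.57 ± 0.12); its reads cannot be told with certainty from those of its near-identical neighbour Hspa1a. Fcrls, an Fc receptor-like gene of tissue macrophages, rose from 314 ± 3.09 to 562 ± 38.1 CPM (0.84 ± 0.10). Il7r, the interleukin 7 receptor, fell from 126 ± 6.27 to 70.1 ± 1.88 CPM (-0.85 ± 0.10) and Fbxo32, a ubiquitin ligase subunit, from 103 ± 1.38 to 59.0 ± 4.10 CPM (-0.81 ± 0.10). Under edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.00719 for Gpnmb and Hspa1b, 0.0380 for Il7r, 0.0398 for Fcrls and 0.0487 for Fbxo32. In all, 3 genes rose and 7 fell of 12301 tested (DESeq2 called 101), with the treatments apart in 43.1% of genes against 33.3% by chance. Left-out libraries gave counts of 118 without untreated 1, 243 without untreated 2, and 0 without entinostat 1 or entinostat 2, where edgeR gave 1627 and 1078 genes at an unadjusted p under 0.05. Log2 changes of Gpnmb were then -2.01 and -1.62, of Hspa1b 1.68 and 1.46, of Fcrls 0.77 and 0.91, of Il7r -0.88 and -0.82, and of Fbxo32 -0.74 and -0.88. Without a filter on low counts edgeR called 0 genes (1517 at an unadjusted p under 0.05) and all 5 calls ended; with doublets kept those of Fcrls, Il7r and Fbxo32 ended, with each library clustered on its own those of Il7r and Fbxo32, and with thinning that of Fbxo32.

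A macrophage-like cluster led by Gpnmb, Mmp12, Ctsl and Arg1 held 234 and 203 cells of the untreated libraries and 113 and 47 of the entinostat libraries. The values within the class therefore cover different mixtures of clusters. Fibroblast markers were higher in this class too (6 of 6, median log2 change 1.15). So were epithelial markers in 10 of 12 cases (0.32) and basal epithelial markers in 3 of 3 (1.61), whereas B-lineage markers were lower in 3 of 5 (-0.51).

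Antigen presentation and interferon genes of macrophage-like cells differed between treatments. Genes of major histocompatibility complex (MHC) class II presentation were higher in 11 of 12 cases, with a median log2 change of 0.54, and 6 passed when adjusted over the list alone (0 over all genes). H2-Ab1, a class II beta chain, went from 2548 to 3787 CPM (0.57 ± 0.16), H2-DMa, which helps load peptides, from 178 to 253 CPM (0.51 ± 0.11) and Ciita, the transactivator of class II genes, from 10.2 to 15.5 CPM (0.60 ± 0.20). Markers of dendritic cells, which are rich in MHC class II, were higher in the class in 7 of 8 cases (median 0.38). Type I interferon response genes were lower in 19 of 19 cases (median log2 change -0.90), with 7 passing when adjusted over the list alone and 0 over all genes. Among these, the antiviral gene Rsad2 went from 124 to 49.9 CPM (-1.31 ± 0.31). By limma's camera test with a preset correlation, MHC class II genes rose (Benjamini-Hochberg adjusted p = 0.000311) and interferon genes fell (adjusted p = 2.73e-05), and for each adjusted p = 0.953 with an estimated correlation. Median log2 changes of the interferon genes were -0.12 without untreated 1 and -1.50 without untreated 2, and that of MHC class II genes was 0.25 without entinostat 2. Of 14 complement and lysosome genes, 7 lower and 3 higher passed when adjusted over the list alone, among them the cathepsin genes Ctsl (3399 to 1128 CPM, -1.59 ± 0.33) and Ctsd (7785 to 5139 CPM, -0.60 ± 0.13); the group's call (median -0.27, camera adjusted p = 0.0378, adjusted p = 0.953 with an estimated correlation) ended without untreated 2 (-0.21), entinostat 1 (-0.31) or entinostat 2 (-0.21).

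In epithelial-like tumour cells, genes of the cell cycle were higher with entinostat. Of 35 G2/M genes 34 were higher (median log2 change 0.71), and of 31 S phase genes 31 (median 0.51); 26 and 16 of them passed when adjusted over the list alone and 0 over all genes. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, went from 42.0 to 74.8 CPM (0.83 ± 0.09), the cyclin gene Ccnb2 from 10.3 to 18.1 CPM (0.82 ± 0.13) and Mcm5, part of the replicative helicase, from 8.09 to 14.0 CPM (0.80 ± 0.11). All 12 heat shock genes were higher (median 0.44, 6 passing when adjusted over the list alone and 0 over all genes), including Hspa1b (67.3 to 294 CPM, 2.13 ± 0.34) and Hspb1, a small heat shock protein (1154 to 2066 CPM, 0.84 ± 0.14). By limma's camera test with a preset correlation, G2/M (Benjamini-Hochberg adjusted p = 2.30e-17), S phase (4.49e-12) and heat shock genes (2.73e-05) rose; for each, adjusted p = 0.953 with an estimated correlation.

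No single gene of the epithelial-like class passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment: 0 of 16147, with 1781 at an unadjusted p under 0.05 and 364 called by DESeq2. Without entinostat 1 the count was 262 and without entinostat 2 it was 240. The treatments were apart in 43.9% of epithelial-like genes against 33.3% by chance. Epithelial-like clusters differed in size between treatments, among them those led by Krt17 with Hspa1b and Cryab, by Fcgbp and Lalba, and by the secretory genes Car6 and Pip. A cluster of cycling cells, led by Birc5, Ube2c and Cdc20, held 112 of 3129 and 97 of 3702 epithelial-like cells in the untreated and 285 of 3866 and 172 of 2342 in the entinostat libraries. Fibroblast markers were higher here in 9 of 10 cases (median log2 change 1.62), endothelial markers in 9 of 9 (0.51) and neutrophil markers in 9 of 10 (0.50).

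**Figure D2:**
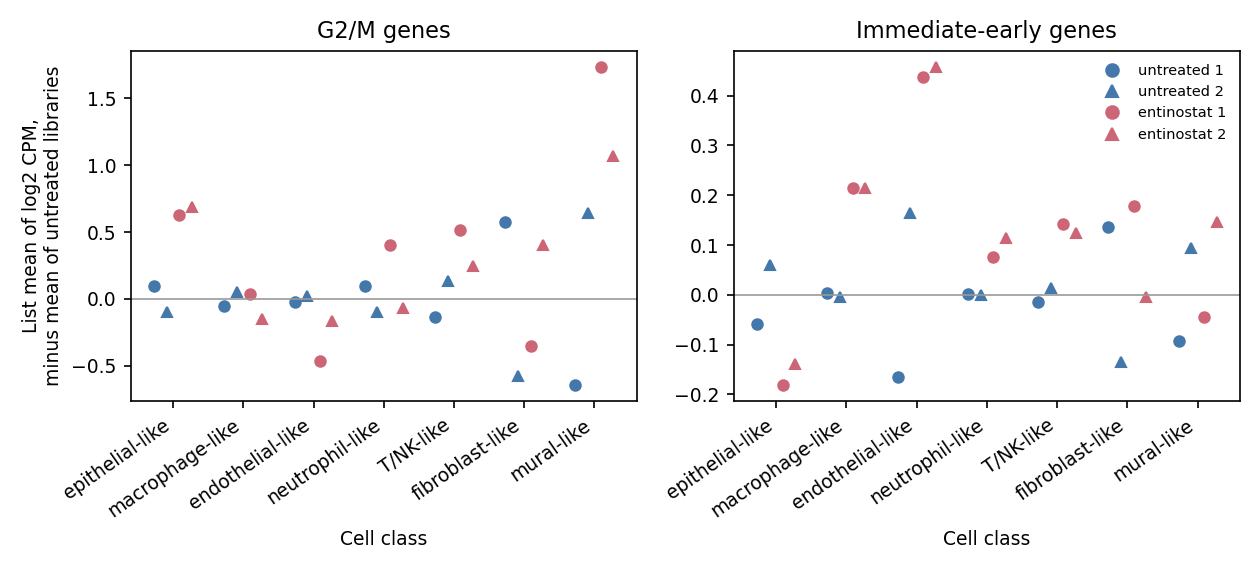
Mean log2 CPM of G2/M genes (left) and immediate-early genes (right) in each library and cell class, minus the mean of the untreated libraries of that class. Points stand for libraries; G2/M levels of both entinostat libraries lay above both untreated libraries in epithelial-, T/NK- and mural-like cells and below them in endothelial-like cells.

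Vessel-associated cells differed in opposite directions in G2/M genes. In mural-like cells 31 of 31 G2/M genes were higher with entinostat (median log2 change 1.25, 26 passing when adjusted over the list alone and 0 over all genes) and 23 of 24 S phase genes were higher (0.67, 5 and 0). Ccnb2 went from 13.4 to 49.1 CPM (1.78 ± 0.35), and Tpx2, a spindle assembly factor, from 20.6 to 52.5 CPM (1.25 ± 0.31). In endothelial-like cells 33 of 35 G2/M genes were lower (median -0.31, 0 passing when adjusted over the list alone or over all genes), such as Cdc20, an activator of the anaphase-promoting complex (58.3 to 38.0 CPM, -0.63 ± 0.17). Their S phase genes went both ways without passing (17 higher and 14 lower, median 0.02, camera adjusted p = 0.901). Immediate-early genes were higher in endothelial-like cells in 14 of 14 cases (median 0.45, 13 when adjusted over the list alone and 0 over all genes), among them the transcription factor genes Jun (1497 to 2166 CPM, 0.53 ± 0.12) and Junb (2093 to 3075 CPM, 0.55 ± 0.14). Camera with a preset correlation put the Benjamini-Hochberg adjusted p at 7.70e-18 for mural G2/M, 8.74e-10 for mural S phase, 6.77e-07 for endothelial G2/M and 2.77e-08 for endothelial immediate-early genes; for each, adjusted p = 0.953 with an estimated correlation. The mural G2/M median was 2.20 without untreated 2 and 0.74 without entinostat 1, and the endothelial G2/M median -0.20 without entinostat 1.

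Among single genes of the vessel-associated classes, Errfi1, a feedback inhibitor of epidermal growth factor receptor signalling, rose in mural-like cells from 419 ± 37.8 to 826 ± 50.6 CPM (n = 2 libraries each; log2 change 0.98 ± 0.13, SE). Tmem252, a membrane protein gene, rose in endothelial-like cells from 182 ± 28.9 to 387 ± 25.3 CPM (1.08 ± 0.13). Adjusted p was 0.0380 and 0.0467 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all, 2 genes rose and 3 fell of 9906 in mural-like cells, and 2 rose and 0 fell of 11144 in endothelial-like cells; DESeq2 called 12 and 22. The macrophage genes Apoe, Lyz2 and Wfdc17 fell in mural-like cells, where Apoe stood at 1.40% of its macrophage-like level. Cxcl2, a chemokine gene, was called in endothelial-like cells at mean levels of 65.1 and 137 CPM, but its log2 change was -0.16 with doublets kept. In mural-like cells macrophage markers were lower in 8 of 8 cases (median -1.43) and neutrophil markers in 9 of 10 (-0.70), whereas epithelial markers, of the class whose cell cycle genes were higher too, were higher in 9 of 10 (0.63, 1 of them called). In endothelial-like cells neutrophil markers were lower in 3 of 5 cases (-1.36) and mural markers lower in 7 of 9 (-0.46). Epithelial markers were higher there in 8 of 10 (0.33) and fibroblast markers in 2 of 5 (-0.19). The set of 36 epithelial genes overlapped between treatments in both classes. Its pairs of libraries ran from -0.71 to 1.42 in mural- and from -0.49 to 1.02 in endothelial-like cells. The treatments were apart in 39.9% of mural-like and 39.4% of endothelial-like genes against 33.3% by chance. Counts without untreated 1, untreated 2, entinostat 1 and entinostat 2 were 1, 36, 87 and 322 in mural-like and 55, 130, 201 and 148 in endothelial-like cells, and the calls of Errfi1 (0.89), Lyz2 (-1.11) and Wfdc17 (-1.57) ended without untreated 1. With each library clustered on its own the calls of Tmem252 (1.09), Cxcl2 (1.11), Errfi1 (1.02), Lyz2 (-1.25) and Wfdc17 (-1.31) ended, that of Lyz2 also with doublets kept (-0.69), and DESeq2 did not call Cxcl2.

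In T/NK-like cells, Gzmc, which encodes a granzyme of cytotoxic lymphocytes, rose from 65.8 ± 14.2 to 486 ± 296 CPM (mean ± SD, n = 2 libraries each, log2 change 2.90 ± 0.36, SE). The list of T cell cytotoxicity genes did not pass, with 5 of 13 higher and 8 lower (median -0.08, camera adjusted p = 0.676). Hspa1b rose from 37.1 and 4.15 CPM to 162 and 164 CPM (3.0 ± 0.44), with the same uncertainty towards Hspa1a. Hspb1, at 8.55% of its highest class, rose from 44.5 ± 18.9 to 241 ± 50.7 CPM (2.45 ± 0.26). For Gzmc, Hspa1b and Hspb1, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.0108, 0.0453 and 0.00478; these were the 3 genes called of 8166 (DESeq2 called 5). The treatments were apart in 35.9% of genes against 33.3% by chance. Left-out libraries gave 6, 53, 83 and 156 called genes (without untreated 1, untreated 2, entinostat 1 and entinostat 2), and the call of Gzmc ended without untreated 1 (log2 change 2.70). With each library clustered on its own the calls of Gzmc (2.90), Hspa1b (2.98) and Hspb1 (1.29) ended. A robust fit kept only that of Hspb1, which ended with the stricter cell filter (1.44), and Hspa1b was not called by DESeq2 (2.99) or with DESeq2's size factors in edgeR.

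Heat shock genes of T/NK-like cells were higher in 11 of 12 cases (median 0.34, 5 passing when adjusted over the list alone and 2 over all genes). Genes of regulatory T cells were higher in 8 of 11 cases (median 0.20, 5 passing when adjusted over the list alone and 0 over all genes), among them the costimulatory receptors Tnfrsf4 (68.8 to 210 CPM, 1.57 ± 0.30) and Tnfrsf18 (129 to 240 CPM, 0.89 ± 0.18), the checkpoint receptor Ctla4 (100.1 to 175 CPM, 0.80 ± 0.18) and Foxp3, the lineage factor of these cells (34.5 to 70.2 CPM, 0.98 ± 0.25). The camera test with a preset correlation gave Benjamini-Hochberg adjusted p = 1.68e-05 for heat shock genes and 0.0242 for regulatory T cell genes, and adjusted p = 0.953 with an estimated correlation for each. Epithelial markers in the class were higher in 8 of 10 cases (median log2 change 0.79) and fibroblast markers in 3 of 3 (1.43). Macrophage markers were lower in 6 of 9 (-0.96) and neutrophil markers in 3 of 3 (-2.03). The cluster led by Tnfrsf4 and Ctla4 held 140 of 276 and 130 of 283 cells of the class in the untreated libraries. In the entinostat libraries it held 143 of 206 and 201 of 358, so that the class's mixture of clusters differed as well. The cluster with Gzmb and Gzmc among its leading genes held 65 and 93 of these cells in the untreated and 38 and 97 in the entinostat libraries. Heat shock genes had a median of 0.54 without entinostat 1, and the call of regulatory T cell genes ended without untreated 1 (0.12) and entinostat 2 (0.18), with a median of 0.32 without untreated 2.

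**Figure D3:**
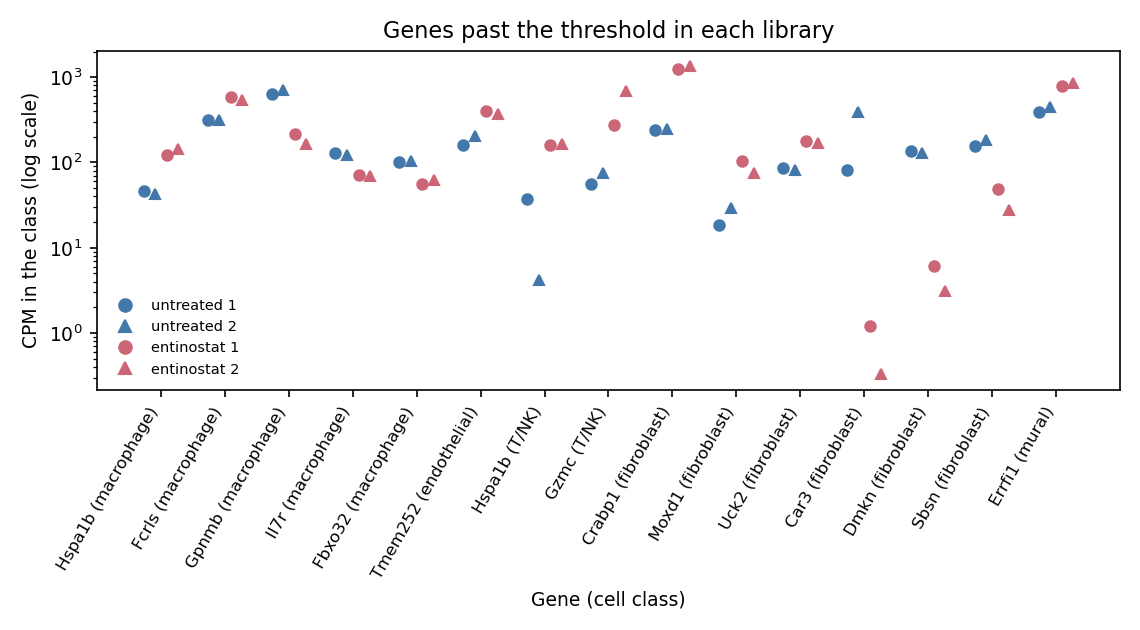
CPM (log scale) of the genes past the threshold that the naming rule picked, with 1 point per library; the cell class stands in brackets. In each gene both entinostat libraries lay on the same side of both untreated libraries, as with Crabp1 in fibroblast-like cells (239 and 249 against 1246 and 1347 CPM).

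Neutrophil-like cells gave no called gene: 0 of 5429 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 290 at an unadjusted p under 0.05 and 0 called by DESeq2. Their summed depth was the lowest of the 7 classes, at 473612 to 608031 UMIs per library. The treatments were apart in 33.2% of neutrophil-like genes against 33.3% by chance. Counts were 10, 22, 84 and 38 without untreated 1, untreated 2, entinostat 1 and entinostat 2. Epithelial markers in these cells were lower in 9 of 10 cases (median log2 change -0.99) and fibroblast markers higher in 3 of 3 (1.47).

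Expression of the drug's targets and of genes often followed under deacetylase inhibition was read next. H1f0, a linker histone gene, was higher with entinostat in 7 of 7 classes, with log2 changes from 0.15 to 0.94, such as 142 ± 3.20 to 204 ± 8.73 CPM in fibroblast-like cells (0.52 ± 0.11, n = 2 libraries each). The 9 genes followed in every class (Cdkn1a, H1f0, Hdac1, Hdac2, Hdac3, H2-K1, B2m, Cd274 and Mki67) gave 60 values, of which 0 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and 10 had an unadjusted p under 0.05; the smallest adjusted p was 0.126. Cdkn1a, an inhibitor of cyclin-dependent kinases, differed by 0.56 in endothelial-like cells (191 ± 11.5 to 281 ± 4.22 CPM) and by -0.34 in fibroblast-like cells (268 ± 40.0 to 212 ± 5.10 CPM). Hdac1, one of the drug's targets, lay between -0.05 and 0.25 across classes, Hdac2 between -0.10 and 0.24 and Hdac3 between -0.15 and 0.23. Cd274, the checkpoint ligand PD-L1, lay between -0.86 and 0.28.

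Over all gene groups, those above included, of 177 tests of a list in a class, 44 passed limma's camera test with a preset correlation of 0.01 and Benjamini-Hochberg adjustment, 35 higher and 9 lower. None passed with an estimated correlation (smallest adjusted p = 0.953 with an estimated correlation, smallest unadjusted p = 0.0176) or by limma's fry test (smallest adjusted p = 0.186). List means of the treatments were apart in 40 of the 44 called tests and overlapped in 4. Leaving out any 1 library kept 20 of the 44 calls. Genes encoded by the mitochondrial genome were higher in 7 of 7 classes (medians 0.08 to 0.51) and passed in 6, for example in macrophage-like cells, where 13 of 13 were higher (median 0.49, 12 passing when adjusted over the list alone and 0 over all genes); this was the measure on which barcodes were filtered. Their calls ended without untreated 1 in neutrophil- (0.29), endothelial- (0.19) and fibroblast-like cells (0.20) and without entinostat 1 in endothelial- (0.08) and fibroblast-like cells (0.09), where the medians without entinostat 2 were 0.49 and 0.53. Ribosomal protein genes, followed as a measure of RNA quality, passed in macrophage- (29 of 29 higher, median 0.16, adjusted p = 2.73e-05) and endothelial-like cells (28 of 29, 0.18, adjusted p = 0.000125), with 0 passing when adjusted over the list alone or over all genes and adjusted p = 0.953 with an estimated correlation. The endothelial call of these genes ended without untreated 1 (0.11).

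Communication between classes was measured as the sum of the log2 CPM of a ligand in a sender class and of its receptor in a receiver class, with CPM scaled over all genes rather than those tested. Neutrophil-like Cd80, a costimulatory ligand, with T/NK-like Ctla4, its inhibitory receptor, was higher with entinostat by 1.64 ± 0.29 (SE, n = 2 libraries each). Fibroblast-like Il33, an alarmin, with Il1rl1 of the same cells was lower by a log2 difference of -2.99 ± 0.37, from 29.9 and 28.6 to 1.70 and 2.31 CPM of Il1rl1 while Il33 stood at 279 and 348 against 347 and 453 CPM. Of 1534 combinations of 141 ligand-receptor pairs, limma with Benjamini-Hochberg adjustment called 0; 173 had an unadjusted p under 0.05 (74 higher), and the smallest adjusted p was 0.203. The other combinations named by rank rest on a gene at a low level against the class where it is highest. Those of neutrophil-like Postn with Itgav of T/NK-, macrophage- or endothelial-like cells (2.30, 2.34 and 2.61) used Postn at 0.508% of its fibroblast-like level. Those of mural-like Apoe with Lrp1 or Trem2 (-2.45 to -2.96) used Apoe at 1.40% of its macrophage-like level. App with Cd74 from T/NK- to endothelial-like cells (1.78) used Cd74 at 0.330% of its highest level. Counts of called combinations were 1, 40, 64 and 78 without untreated 1, untreated 2, entinostat 1 and entinostat 2.

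A further test, chosen after these low levels were seen, kept 746 combinations in which ligand and receptor each reached at least 20% of the class where they were highest. It called the fibroblast-like Il33 and Il1rl1 combination (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0447, against 0.203 over all combinations). Wnt5a with its receptor Ror2 within fibroblast-like cells was higher by 1.65 ± 0.42 without passing. The guidance factor Sema3c of fibroblast-like cells with Nrp2 of macrophage-like cells (-2.17 ± 0.36) and the Notch ligand Dll1 with Notch1 within epithelial-like cells (-2.23 ± 0.41) were lower without passing.

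B cells were few. The receptor libraries held 49 and 21 cells with a productive heavy chain in the untreated and 16 and 54 in the entinostat samples (35 ± 19.8 and 35 ± 26.9, mean ± SD, n = 2 each, exact two-sided permutation p = 1.0). Most carried IgM, the isotype of unswitched B cells: 87.8% (95% Wilson interval 75.8 to 94.3), 21 of 21 cells (84.5% or more), 81.3% (57.0 to 93.4) and 81.5% (69.2 to 89.6) in untreated 1, untreated 2, entinostat 1 and entinostat 2, with an exact permutation p = 0.333. IgG was found in 0 cells, which allows shares of up to 6.12%, 14.3%, 18.8% and 5.56%. A clonotype shared by 2 cells occurred in untreated 1 and in entinostat 2, and no larger one was found. The transcriptome libraries held 48, 20, 11 and 53 B-lineage-like cells, too few to compare expression.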

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

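The tests of a difference between cell classes in this part were all chosen only after the results were seen. They cover gene groups that passed their test in opposite directions in a pair of classes, which is what drew attention to them. Because of that choice, camera with its preset correlation was bound to pass for the difference as well, so its p supports nothing and is not given. The effect is the mean over the genes of the log2 difference of entinostat minus untreated, and p is that of limma's camera test of the difference of effects with an estimated correlation. With Benjamini-Hochberg adjustment over the 6 differences, none passed (smallest adjusted p = 0.1798, 1 with an unadjusted p under 0.05).

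The effect on G2/M genes was 1.69 higher in mural- than in endothelial-like cells (31 genes, unadjusted p = 0.162 with an estimated correlation). Epithelial-like tumour cells exceeded endothelial-like cells in the G2/M effect by 0.97 (35 genes, unadjusted p = 0.0599 with an estimated correlation). T/NK-like cells exceeded endothelial-like cells by 0.68 (27 genes, unadjusted p = 0.122 with an estimated correlation). Median log2 changes of G2/M genes moved by more than 1.5 times without 1 library in mural- (2.20 without untreated 2, 0.74 without entinostat 1), endothelial- (-0.20 without entinostat 1) and T/NK-like cells (0.56 without untreated 2, 0.43 without entinostat 2).

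The effect on immediate-early genes, which respond within minutes to stimuli and to tissue dissociation, was 0.61 higher in endothelial- than in epithelial-like cells (14 genes, unadjusted p = 0.0978 with an estimated correlation). Macrophage-like cells exceeded epithelial-like cells in the same effect by 0.38 (14 genes, unadjusted p = 0.0451 with an estimated correlation). For NF-κB target genes of inflammation, endothelial-like cells exceeded epithelial-like cells by 0.62 (14 genes, unadjusted p = 0.220 with an estimated correlation). In epithelial-like cells the call of immediate-early genes ended without untreated 2 (median log2 change -0.10), entinostat 1 (-0.19) or entinostat 2 (-0.19) and the median was -0.22 without untreated 1. The call of NF-κB genes ended without untreated 2 (-0.09) or entinostat 2 (-0.11) in epithelial-like cells and without untreated 1 (0.20) in endothelial-like cells, where the median was 0.24 without entinostat 2.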

How the results depend on the processing

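The robust fit, DESeq2's size factors within edgeR and the ligand-receptor minimum of 20% of the highest class were chosen only after the data were seen, while the other alternatives were planned. Called genes numbered 0 in epithelial-, 10 in macrophage-, 2 in endothelial-, 0 in neutrophil-, 3 in T/NK-, 28 in fibroblast- and 5 in mural-like cells under edgeR's quasi-likelihood test (1781 epithelial- and 290 neutrophil-like genes had an unadjusted p under 0.05). DESeq2 gave 364, 101, 22, 0, 5, 129 and 12. Without a filter on low counts the counts were 0 in macrophage- (1517 genes at an unadjusted p under 0.05), 227 in endothelial-, 28 in neutrophil-, 86 in T/NK-, 681 in fibroblast- and 201 in mural-like cells. A robust fit called 79 macrophage-, 7 endothelial-, 12 T/NK- (1 of the 3 shared) and 99 fibroblast-like genes (25 of the 28 shared). With doublets kept the counts were 3 in macrophage-, 3 in neutrophil-, 14 in T/NK- and 15 in mural-like cells. The stricter cell filter gave 13 T/NK- and 17 mural-like genes, thinning 14 endothelial-like genes, and leaving out genes under 10% of their highest class 20 T/NK-, 67 fibroblast- and 1 mural-like gene. Clustering each library on its own gave 0 endothelial- (822 at an unadjusted p under 0.05), 1 T/NK- (none of the 3) and 1 mural-like gene (1 of the 5). In the other 45 cases a count stayed within 1.5 times, and the cause of the moves was not tested.

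Leaving out each library in turn gave 0 to 262 called genes in epithelial-, 0 to 243 in macrophage-, 55 to 201 in endothelial-, 10 to 84 in neutrophil-, 6 to 156 in T/NK-, 22 to 661 in fibroblast- and 1 to 322 in mural-like cells, 39 to 49 called lists and 1 to 78 called ligand-receptor combinations. These fits have a lone sample in a group, which is assumed to vary like the other group. The share differences (entinostat minus untreated) moved for macrophage-like cells from -3.11 points to -3.44 with doublets kept, -4.11 with the stricter filter, -4.81 with each library clustered on its own and -8.24 among cells other than epithelial. Among those cells the differences were also 3.92 points for endothelial- (2.44 of all cells), -1.37 for neutrophil- (-0.33) and 6.71 for fibroblast-like cells (3.71), and the stricter filter gave -0.78 for neutrophil-like cells. Lists called fell from 44 to 0 with an estimated correlation and to 0 with fry, where the smallest adjusted p was 0.953 and 0.186. Of the 44 calls, 44 were kept with DESeq2's size factors and 39 without a filter. The ligand-receptor count of 0 (limma, 173 at an unadjusted p under 0.05) became 1 at 20% of the highest class, where fewer combinations were tested.

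The 17 called genes that were named by rule kept their call in 211 of 252 values under the alternatives and lost it in 40, with the direction kept. Called genes picked after their values were seen, such as Adipoq, Pck1, Lyz2 and Wfdc17, are not counted here. The 179 named genes that were not called stayed uncalled in 2344 of 2665 values and passed in 318. Directions turned in endothelial-like cells with doublets kept for Cxcl2 (log2 change -0.16), Cd74 (-1.17), H2-Ab1 (-1.11) and H2-DMa (-0.23), and for App of T/NK- with Cd74 of endothelial-like cells (-0.83); the cause was not tested. Among the values of genes followed in every class, 50 with an unadjusted p of 0.05 or more were not followed one by one, and 22 of these changed sign under at least 1 alternative. B cell receptor values moved by less than the spread between libraries in 35 of 35 cases.

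The labels do not say whether equal replicate numbers pair the samples. Gene by gene, the difference between replicates of untreated samples had a Pearson r with that of entinostat samples of -0.04 to 0.19 across genes. Values this low show no large effect shared over genes as a whole, but cannot exclude a pairing or shared effects on some gene groups. Hypoxia genes of macrophage-like cells stood at 6.29 and 5.54 mean log2 CPM in untreated 1 and untreated 2, and at 6.11 and 5.25 in entinostat 1 and entinostat 2. Other groups differed in opposite directions, such as G2/M genes of fibroblast-like cells (4.29 and 3.13 against 3.36 and 4.11). With the replicate block the counts were 3, 274, 299, 4, 38, 160 and 25 genes in the order above, 44 lists (41 shared) and 32 ligand-receptor combinations. Depth was lowest in neutrophil-like cells (473612 to 608031 UMIs per library), where 2-fold changes were recovered in 23% and 21% of cases under the 2 simulations. Depth alone does not set this, since epithelial-like cells, at the greatest depth, gave 56% and 0%.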

Other observations

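The tests of explanations in this part were chosen only after the results were seen, whereas the gene lists and their tests were planned. In endothelial-like cells NF-κB target genes of inflammation rose by camera with a preset correlation: 12 of 15 were higher, with a median log2 change of 0.45, 4 when adjusted over the list alone and 1 over all genes. They included Nfkbia, the inhibitor of NF-κB (736 to 1096 CPM, 0.57 ± 0.18, n = 2 libraries each), and the cytokine gene Il6 (18 to 29.5 CPM, 0.72 ± 0.19). In epithelial-like cells 15 of 16 of them were lower (median -0.22, 0 when adjusted over the list alone and over all genes), such as Tnfaip3, a feedback inhibitor (75.5 to 54.5 CPM, -0.47 ± 0.11), and the list fell. Camera's Benjamini-Hochberg adjusted p was 4.28e-05 and 0.00947, and adjusted p = 0.953 with an estimated correlation for both. The endothelial call ended without untreated 1 (0.20; 0.24 without entinostat 2) and the epithelial call without untreated 2 (-0.09) or entinostat 2 (-0.11). Hypoxia genes of endothelial-like cells passed as well (11 of 14 higher, median 0.17, 2 when adjusted over the list alone and 0 over all genes), led by Ddit4, a stress-induced inhibitor of growth signalling (238 to 413 CPM, 0.79 ± 0.13), with adjusted p = 0.0217 and adjusted p = 0.953 with an estimated correlation. List means of the treatments overlapped (5.77 and 5.42 log2 CPM untreated, 5.98 and 5.71 entinostat). The hypoxia call ended without untreated 2 or entinostat 1 (0.04 each), and the median was 0.31 without untreated 1 and 0.30 without entinostat 2.

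Genes of alternatively activated macrophages fell in macrophage-like cells (11 of 15 lower, median log2 change -0.49, 1 when adjusted over the list alone and 1 over all genes), with Spp1, the gene of osteopontin, at 6285 and 4466 CPM (-0.49 ± 0.18) beside Gpnmb. Histone genes passed in 6 classes, among them mural-like cells, where 11 of 11 were higher (median 0.40, 3 when adjusted over the list alone and 0 over all genes), among them the variant histone gene H2afz (426 to 673 CPM, 0.65 ± 0.16). G2/M genes of T/NK-like cells rose (23 of 27 higher, median 0.27, 1 when adjusted over the list alone and 0 over all genes), led by Ube2c (38.1 to 98.3 CPM, 1.33 ± 0.27). Camera's Benjamini-Hochberg adjusted p was 0.0224 for the macrophage list, 0.000856 for mural histones and 1.05e-05 for G2/M genes, and adjusted p = 0.953 with an estimated correlation for each. The macrophage call ended without untreated 2 (-0.29) or entinostat 2 (-0.15); medians were 0.27 without untreated 1 for mural histones, and 0.56 without untreated 2 and 0.43 without entinostat 2 for G2/M genes. Only mural-like cells kept the histone call without each library in turn: it ended in endothelial- (0.12), macrophage- (0.14), epithelial- (0.31) and T/NK-like cells (0.21) without untreated 1, and in fibroblast- (0.16) and T/NK-like cells (0.37) without untreated 2. It also ended in macrophage- (0.20) and T/NK-like cells (0.10) without entinostat 1, and in epithelial- (0.22) and T/NK-like cells (0.30) without entinostat 2. The list of genes induced by deacetylase inhibitors was higher in T/NK-like cells (8 of 11, median 0.36, 2 when adjusted over the list alone and 0 over all genes, camera adjusted p = 0.0410, adjusted p = 0.953 with an estimated correlation). Its call ended without untreated 2 (0.21) or entinostat 1 (-0.01). In no other class did this list pass. There its mean log2 CPM differed by 0.13 in epithelial-, 0.17 in macrophage-, 0.03 in endothelial-, -0.03 in neutrophil-, -0.16 in fibroblast- and 0.14 in mural-like cells.

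Among the receptor libraries, the largest contig of entinostat 2 held 19274 UMIs, against 140, 88 and 80 in untreated 1, untreated 2 and entinostat 1. It was a kappa light chain, and the same B-lineage-like cell carried an IgA heavy chain with 9242 UMIs and 21011 transcriptome UMIs.

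Fibroblast genes were higher with entinostat inside epithelial-, macrophage-, neutrophil- and T/NK-like cells, while fibroblast-like cells held 3.20% and 3.13% of the UMIs kept in untreated and 5.24% and 9.03% in entinostat libraries. RNA of fibroblasts in the droplets of other cells could raise them: the summed CPM of 27 genes at least 20 times higher in fibroblast-like than in every other class was higher by a log2 difference of 0.44 in epithelial-, 0.51 in macrophage-, 1.06 in neutrophil- and 0.14 in T/NK-like cells, but only by 0.31 in endothelial-like (pairs of libraries from -0.34 to 0.96) and by -0.03 in mural-like cells (-0.23 to 0.17), where such RNA would be due as well. That explanation stays open, since the pairs of libraries ranged from -0.00 to 0.28 in T/NK-like cells on as few as 41 UMIs and from 0.41 to 1.72 in neutrophil-like cells on as few as 30, while the level of 162 and 209 CPM in untreated mural-like cells could hide a rise of the size in macrophage-like cells (53.4 and 54.0 to 70.8 and 82.3 CPM). A test of single genes came first (medians 1.11 in epithelial-, 0.57 in macrophage-like cells) and covered too few classes. A wider set of 146 genes at 5 times the classes other than mural- and endothelial-like gave 0.27, 0.06, 0.55 and 0.38. Its pairs of libraries ran from -0.0015 to 0.54 in epithelial-, -0.02 to 0.15 in macrophage-, 0.27 to 0.84 in neutrophil- and 0.12 to 0.64 in T/NK-like cells. In epithelial-like cells it stood at 2224 CPM in entinostat 1 but 1537 in entinostat 2, against 1534 and 1539 untreated. Fibroblast-like cells held the larger share of UMIs in entinostat 2. Expression by the cells themselves stays open too. Levels in epithelial-like cells did not follow those in fibroblast-like cells (Pearson r = -0.13 across 26 genes, which are not independent replicates). The genes were chosen for low levels outside fibroblast-like cells, and r covers levels over all libraries rather than the change, so it cannot decide. In macrophage-like cells r was 0.27 across 7 genes, and neutrophil- and T/NK-like cells had too few genes to decide. Levels in mural-like cells, which showed no rise, did follow (r = 0.94 across 7 genes).

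Heat shock genes were higher with entinostat in epithelial- and T/NK-like cells, and Hspa1b in 7 of 7 classes (log2 changes 0.11 to 3.0). Stress of tissue dissociation raises immediate-early genes too, and no such rise was seen in epithelial-like cells. Of those genes 13 of 14 were lower (median log2 change -0.13), with list means of 10.89 and 10.93 log2 CPM with entinostat against 11.01 and 11.13. The sign held without any 1 library (-0.22 to -0.10). The fall was small, with adjusted p = 0.953 by camera with an estimated correlation, and these genes were high in every library. A rise of both groups of genes together is thus not borne out there, but dissociation stress is not excluded. Immediate-early genes were higher in endothelial- (0.45, beside a heat shock median of 0.00) and macrophage-like cells (0.25) and had a median of 0.14 without passing in T/NK-like cells, where dissociation stays open. RNA of epithelial cells in T/NK droplets could not be excluded: 36 epithelial genes at 5 times the other classes differed by 0.46, with pairs of libraries from -0.51 to 1.43. A bar of 1.23 had been set from the changes of Hspa1a, Hspa1b and Hspb1 (median 2.45). It cannot decide, since Hspa1b rose in epithelial-like cells too (2.13) and such RNA would carry that rise. With entinostat Hspa1b stood at 162 and 164 CPM in T/NK-like against 194 and 394 CPM in epithelial-like cells. Epithelial RNA would have to be a large part of the T/NK-like RNA to give that level of Hspa1b alone, if it matched the mean of epithelial-like cells. A smaller part would do for Hspb1, which stood far lower in T/NK- than in epithelial-like cells. The epithelial-like cluster with Krt17, Hspa1b, Hspa1a and Cryab among its leading genes held 270 of 3129 and 427 of 3702 untreated epithelial-like cells. In the entinostat libraries it held 1271 of 3866 and 499 of 2342. The mixture of clusters thus differed, and changes within clusters were not tested. The treatment itself may raise heat shock genes in epithelial-like cells, a hypothesis that these data cannot separate from this mixture or from differences between the samples or their preparation.

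Type I interferon genes were lower with entinostat in macrophage-like cells in 19 of 19 cases. A candidate explanation is that untreated 1 alone stands apart: without it the median log2 change was -0.12, with 13 of 19 lower. In epithelial-like cells the median was -0.32 without passing, 0.21 without untreated 1 and -0.73 without untreated 2, and untreated 1 held 286 of the 525 cells of the epithelial-like cluster led by interferon genes. List means in macrophage-like cells were 6.18 and 5.00 log2 CPM in untreated 1 and untreated 2, against 4.66 and 4.90 with entinostat. Most of the fall thus rested on untreated 1. The call kept without that library came from camera with its preset correlation, which cannot decide whether the smaller fall is real. That smaller fall stays open, as does an effect of the treatment, which was not tested apart from untreated 1.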
